A study of Sus scrofa with 9 samples.

How the data were processed

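Kidney biopsies from 9 male Yorkshire pigs were measured on Affymetrix arrays, 1 array per animal, with 3 animals each in the No Storage, SCS and NEVKP groups. Per the labels, all kidneys had 30 min of warm ischemia, SCS and NEVKP lasted 8 h, and biopsies were taken on post-operative day 3. The deposited values are log2 intensities per probe set, made by the authors with RMA, which corrects background, scales arrays to each other and sums up each probe set, per the submitters' processing notes. These notes also name limma 3.34.14. The array type and filters are not given in the sources used here. Raw array scans were not used here.

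All 19124 probe sets were tested. A gene symbol came from the array's annotation, which covered 13680 probe sets and left 5444 without a name. Exactly 1 symbol was given for 13323 and several for 357. Symbol and gene ID disagreed for 7, which left 13316 named probe sets and 12355 genes, 901 of them with several probe sets. A RefSeq gene table gave the same symbol for the gene ID of 12918 named probe sets. A gene was represented by the probe set with the highest mean over all arrays. There were 944 probe sets whose values were identical to those of another, and they were kept. No array was identical to another. The rms SD within groups was 0.238 for No Storage, 0.283 for SCS and 0.301 for NEVKP (n = 3 each), and principal components 1 and 2 held 27.7% and 20.1% of the variance.

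The design, the named-gene rule and the gene lists were fixed before the data were examined. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with default settings) to all 9 arrays with the group as the only factor, giving 6 residual and 4.12 prior degrees of freedom and a prior SD of 0.196. Each kidney came from a different animal, so arrays were treated as independent. Comparisons were SCS with No Storage, NEVKP with No Storage, NEVKP with SCS, and an F test among the groups. P values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of adjusted p under 0.05, and every adjusted p in the text comes from limma. A probe set was called dim when its mean lay under a log2 value of 3.92, the lowest 25%.

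Named genes followed a rule. Part 1 takes, per comparison, up to 10 rises and 10 falls by size among genes past the threshold whose arrays do not overlap, filled up to 10 by smallest unadjusted p and then given as not past. Symbols made of a locus or reading frame number were passed over. Part 2 takes up to 4 members of each list by unadjusted p, of which the text may name fewer in that order. Part 3 takes HAVCR1, LCN2, UMOD and SLC34A1 in each comparison, while PPARGC1A and HMOX1, also fixed, had no named probe set.

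There were 28 lists of at least 5 measured genes, written from general knowledge of genes, with 47% to 86% of their members measured. The 15 pathway lists were oxidative phosphorylation, TCA cycle and mitochondrial biogenesis, fatty acid oxidation and peroxisome, hypoxia and glycolysis, tubular injury and repair, extracellular matrix and fibrosis, inflammatory cytokines and chemokines, interferon response, antigen processing and presentation, complement and coagulation, cell cycle and proliferation, oxidative stress and NRF2 targets, heat shock and unfolded protein response, apoptosis and regulated cell death, and sterol and lipid synthesis. The 13 cell type lists were proximal tubule, loop of Henle and distal tubule, collecting duct, podocyte and mesangium, endothelium, smooth muscle and pericyte, monocyte and macrophage, neutrophil, T and NK cell, B and plasma cell, red cell and platelet, fat and skeletal muscle, and urothelium and mesothelium. Lists were tested with camera in limma at a preset correlation between genes of 0.01, against all 12355 genes, and adjusted over the 28 lists. Camera with the correlation estimated per list, and fry, were the alternatives. Members were also tested adjusted over the list alone.

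The SCS and NEVKP differences from No Storage were compared by correlation and covariance across genes, beside 1000 simulations of unchanged groups that share the No Storage arrays. These simulations drew noise independently for each gene, with the same spread in all groups. Alternatives tried were the replicate number as a block, a trended and robust prior, array weights, omission of the dimmest 25%, centring each array on its median, the mean of a gene's probe sets, a fit on the compared groups alone, and omission of each array in turn. Omission of both arrays of lowest weight, SCS replicate 2 (0.46) and NEVKP replicate 2 (0.57), and of repeated identical probe sets was chosen after seeing the data.

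The steps were tested on simulated data, with normal noise that was alike in all arrays. Array weights in the real data ran from 0.46 to 1.62, so the shares of changes found below may be too high. For SCS against No Storage, with 200 of 19124 probe sets changed in each of 20 simulated sets, limma found 5.74% of those changed by 0.5, 77.8% of those changed by 1 and 98.5% of those changed by 2 on the log2 scale, with 6.18% of calls false. In 100 simulated sets of 12355 genes for the same comparison, camera with preset correlation called 35.5% of unchanged lists whose genes shared a correlation of 0.3, and 0% with an estimated correlation. It called 0.68% of unchanged lists of independent genes, and a list of independent genes shifted by 0.5 in 100% of sets with either correlation. A shifted list of correlated genes was not simulated. How often the estimated correlation misses such a list is therefore not known.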

Results

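Gene expression was measured in biopsies of transplanted pig kidneys, with 1 Affymetrix array per animal and 9 male Yorkshire pigs. Each right kidney was deprived of blood flow for 30 min while warm, flushed, and later returned to the same animal (autotransplantation). No Storage kidneys (n = 3) went back directly. SCS kidneys (n = 3) were kept for 8 h in static cold storage, in which the organ lies in cold solution without flow. NEVKP kidneys (n = 3) spent 8 h in normothermic ex vivo kidney perfusion, in which the organ is perfused near body temperature outside the animal. The left kidney was taken out during the same operation, and the biopsy dates from day 3 after it. The deposited values were log2 intensities of 19124 probe sets. The median log2 value per array ranged from 5.705 to 5.797. Arrays correlated with each other across probe sets at 0.974 to 0.991. The median SD of a probe set within a group was 0.148 for No Storage, 0.193 for SCS and 0.182 for NEVKP (n = 3 each). The number of arrays limits the precision of each comparison.

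The comparison of SCS with No Storage asks how kidneys kept cold before transplantation differ on day 3 from kidneys that were not stored. TIMP1, an inhibitor of matrix metalloproteinases (NCBI Gene ID 396862), rose from 8.76 ± 0.18 to 10.38 ± 0.31 (log2 value, mean ± SD, n = 3), a 3.08-fold difference. LGALS1, the lectin galectin-1 (NCBI Gene ID 414915), rose by 1.45 on the log2 scale (SE 0.19, limma adjusted p = 0.0402). CASQ2, a calcium-binding protein of the sarcoplasmic reticulum (NCBI Gene ID 397436), fell by 1.66 from 8.44 ± 0.16 to 6.78 ± 0.22 (n = 3, limma adjusted p = 0.0123), and RYR2, a calcium release channel, fell by 1.18. The transporter transcripts SLC38A11 and SLC28A2, the latter encoding a sodium-coupled nucleoside transporter, fell by 1.60 (SE 0.18) and 1.35 (SE 0.16), each with a limma adjusted p of 0.0301.

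Among the other genes past the threshold, the adaptor PIK3AP1 rose by 1.33, the integrin subunit ITGB3 by 1.23, the transcription factor MYC by 1.10, the phosphatase DUSP5 by 1.04 and NKAIN1 by 0.93. The transcription factor KLF5 rose by 0.88 and IFNK, an interferon whose probe set was dim, by 0.80. The cytochrome P450 gene CYP2D25 fell by 1.84 (SE 0.29), the esterase gene SIAE by 1.78, the potassium channel gene KCNJ15 by 1.66 and RAB30 by 1.52. The riboflavin transporter gene SLC52A3 fell by 1.26 and the cytochrome P450 gene CYP4F2 by 1.18. SPI1, a transcription factor of myeloid cells, missed the threshold with a log2 difference of 1.03 (limma adjusted p = 0.0513). Of the markers fixed in every comparison, UMOD, the thick ascending limb protein uromodulin, differed by -2.21 (SE 0.49, limma adjusted p = 0.0895) and the phosphate transporter gene SLC34A1 by 1.02 (limma adjusted p = 0.193). The SLC34A1 means, 4.43 in No Storage and 5.45 in SCS, were low and lay below the median of every array. The injury marker LCN2 differed by 0.54 (limma adjusted p = 0.54), and HAVCR1, whose probe set was dim, by -0.06 (limma adjusted p = 0.871).

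In limma, 31 of 19124 probe sets passed an adjusted p of 0.05, 13 higher and 18 lower in SCS. They cover 26 named genes, 9 higher and 17 lower, a further probe set of ALDH1B1, and 4 probe sets without a gene name here. At an unadjusted p under 0.05 there were 2973 probe sets, with 956 expected by chance. The 3 SCS and 3 No Storage arrays did not overlap for any of the 31. Chance gives this for a share of 0.1 of unselected probe sets, and the 31 were selected for large differences between these arrays, so it adds no test. The count depended on single arrays, and all 9 arrays enter the shared estimate of the spread. It was 0, 1 and 0 without No Storage replicates 1, 2 and 3. It was 2, 0 and 147 without SCS replicates 1, 2 and 3, and it was 1, 158 and 2 without NEVKP replicates 1, 2 and 3. CASQ2 passed without 6 of the 9 arrays, SLC38A11 and SLC28A2 without 3, and the other 17 of the 20 called genes named here without 1 or 2. The log2 differences themselves kept their direction over all alternatives, from -1.77 to -1.55 for CASQ2, -1.72 to -1.47 for SLC38A11, -1.50 to -1.26 for SLC28A2, 1.46 to 1.77 for TIMP1 and 1.28 to 1.57 for LGALS1.

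**Figure D1:**
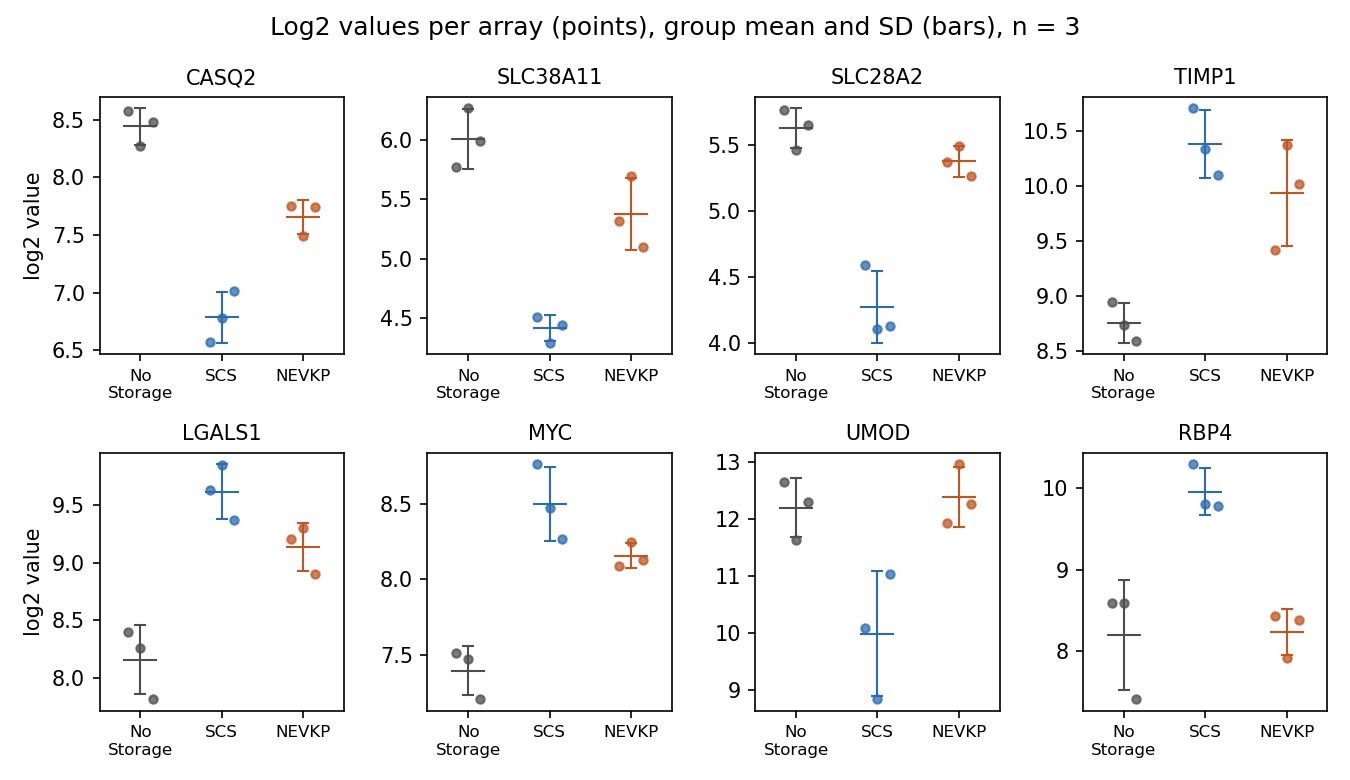
Log2 values (vertical axis) of 8 genes in each array (points) of the No Storage, SCS and NEVKP groups, with horizontal marks for the group mean and bars for the SD (n = 3). For CASQ2, SLC38A11, SLC28A2, TIMP1, LGALS1 and MYC, the SCS arrays lie apart from the No Storage arrays and the NEVKP mean lies between both means, whereas UMOD and RBP4 in NEVKP have means of 12.38 and 8.24, close to 12.20 and 8.20 in No Storage.

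Gene lists fixed before the data were examined moved in SCS toward injury, matrix and cell division transcripts and away from tubule and fatty acid oxidation transcripts in camera with preset correlation. With an estimated correlation 0 of 28 lists passed in camera, with 4 at an unadjusted p under 0.05, and the adjusted p was 0.229 for injury, matrix and fatty acid oxidation, 0.353 for cell cycle and 0.361 for proximal tubule. Among 34 measured genes of tubular injury and repair, 21 rose adjusted over the list alone and 3 over all probe sets, namely ITGB3, MYC and TIMP1. The next was the keratin gene KRT18, at 1.09. Among 36 genes of extracellular matrix and fibrosis, 21 rose adjusted over the list alone and 0 over all (limma). FN1 (fibronectin) rose by 1.28 and the collagen genes COL1A1 by 1.11, COL1A2 by 0.87 and COL5A2 by 0.71. Among 40 genes of cell cycle and proliferation, 12 rose adjusted over the list alone and 0 over all, led by the mitotic kinase gene AURKA (0.91) and HMGB2 (0.81). Of 33 genes of fatty acid oxidation and peroxisome, 17 fell adjusted over the list alone and 0 over all, such as PPARA, a nuclear receptor that drives this pathway (-1.23), ACADS (-0.98) and ACAA1 (-1.20). Of 27 genes of the TCA cycle and mitochondrial biogenesis, 3 fell adjusted over the list alone and 1 over all. These were SLC25A4, the mitochondrial ADP/ATP carrier (-0.77, limma adjusted p = 0.0486), and TOMM20 (-0.65) and PC (-0.86) adjusted over the list alone.

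Tubule segment lists lay lower in SCS in camera with preset correlation, with an adjusted p = 0.361 with an estimated correlation for proximal tubule and an adjusted p = 0.229 with an estimated correlation for loop of Henle and collecting duct. Of 54 proximal tubule genes, 20 fell and 2 rose adjusted over the list alone, and 0 did so over all probe sets in limma. MIOX (-1.33), BHMT2 (-1.21) and AGMAT (-1.12) fell, whereas RBP4, the retinol-binding protein, rose by 1.76. Of 30 collecting duct genes, 10 fell adjusted over the list alone and 0 over all, including SCNN1A, a subunit of the epithelial sodium channel (-0.73), the anion exchanger gene SLC26A7 (-1.86) and the proton pump gene ATP6V0A4 (-1.56). Of 24 genes of the loop of Henle and distal tubule, 4 fell adjusted over the list alone and 0 over all: KNG1 (-1.94), UMOD (-2.21), ATP1B1 (-0.52) and CALB1 (-1.58). The mean of podocyte and mesangium genes lay 0.06 ± 0.14 (SD, n = 3) and that of endothelial genes -0.02 ± 0.15 from the No Storage mean.

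With camera and a preset correlation between genes, 16 of 28 lists differed between SCS and No Storage, 10 higher and 6 lower, and 0 of 28 with an estimated correlation, where 4 had an unadjusted p under 0.05. With the rotation test fry, 4 of 28 passed. The median log2 difference was 0.70 for injury (camera adjusted p = 2.87e-13), 0.63 for matrix (3.97e-17), -0.57 for fatty acid oxidation (1.04e-11), -0.67 for collecting duct (1.05e-08), -0.35 for loop of Henle (2.82e-05), -0.20 for TCA cycle (8.98e-06) and 0.22 for apoptosis and regulated cell death (0.00164), each with an adjusted p = 0.229 with an estimated correlation. It was 0.58 for cell cycle (adjusted p = 1.02e-14, and adjusted p = 0.353 with an estimated correlation) and -0.68 for proximal tubule (adjusted p = 5.07e-10, and adjusted p = 0.361 with an estimated correlation). For inflammatory cytokines and chemokines (0.35, adjusted p = 2.68e-05), oxidative phosphorylation (-0.12, 0.00307), antigen processing (0.15, 0.00658), monocytes and macrophages (0.22, 0.00569) and neutrophils (0.22, 0.0494), it was an adjusted p = 0.378 with an estimated correlation. For the interferon response (0.46, adjusted p = 0.00164) it was an adjusted p = 0.633 with an estimated correlation, and for heat shock (0.12, adjusted p = 0.00669) an adjusted p = 0.492 with an estimated correlation. With centred arrays the heat shock median was 0.07. Members adjusted over the list alone were 2 higher for inflammation (CSF1 0.96 and CCL2 1.59), and 2 higher for heat shock (PDIA6 0.62 and MANF 0.62). They were 2 higher for neutrophils (S100A12 1.51 and CHI3L1 1.74), 1 higher and 1 lower for macrophages (SPI1 1.03 and LST1 -0.67), and 0 for interferon, antigen processing, oxidative phosphorylation and apoptosis.

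Single arrays decided 5 of these SCS list calls. The interferon list (median 0.28) and the antigen processing list (0.09) lost their calls without No Storage replicate 2, the heat shock list (0.06) without SCS replicate 1 and the macrophage list (0.19) without SCS replicate 3. The neutrophil list lost its call without No Storage replicates 1 (0.18) and 3 (0.20), SCS replicates 1 (0.07) and 3 (0.26) and NEVKP replicates 2 (0.22) and 3 (0.22). Some calls were kept without a given array but with medians over 1.5 times smaller. These were TCA cycle without SCS replicate 2 (-0.11), and collecting duct (-0.43), apoptosis (0.14) and macrophages (0.14) without SCS replicate 1. In 5 further cases a median grew over 1.5 times.

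The 12 remaining lists did not pass in SCS against No Storage. Smooth muscle and pericyte genes had a median of 0.32 (camera adjusted p = 0.0589), with CASQ2 lower and the tropomyosin gene TPM2 higher (0.66) adjusted over the list alone. The list passed without SCS replicate 1 (0.21), NEVKP replicate 2 (0.32) or NEVKP replicate 3 (0.32). Sterol and lipid synthesis genes had a median of 0.20 (camera adjusted p = 0.634), with STARD4 (-1.22) and DGAT2 (-0.86) lower and ACACA (0.83) higher adjusted over the list alone. The list passed without SCS replicate 2 (0.37). Medians were 0.05 for hypoxia and glycolysis (camera adjusted p = 0.729), 0.05 for T and NK cells (0.824), 0.08 for B and plasma cells (0.275), and -0.05 for red cells and platelets (0.341). They were -0.12 for fat and skeletal muscle (0.173), 0.02 for podocytes and mesangium (0.468) and 0.0070 for urothelium and mesothelium (0.634). For 3 lists the signs differed. Complement and coagulation had a median of -0.05, a mean of 0.03 and a downward test (camera adjusted p = 0.99). NRF2 targets had a median of -0.02, a mean of 0.11 and an upward test (0.76). Endothelium had a median of -0.00092, a mean of -0.02 and an upward test (0.99). Adjusted over the list alone, the complement list had KNG1 lower and C5 higher (0.74), and the podocyte and fat lists had 1 member each, SULF1 (1.03) and PLIN4 (-1.25).

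The comparison of NEVKP with No Storage asks the same of kidneys perfused warm. The interferon, inflammation, antigen processing and macrophage lists lay higher in NEVKP in camera with preset correlation, without a single probe set past the threshold over the whole array. They had an adjusted p = 0.248 with an estimated correlation for interferon and an adjusted p = 0.218 with an estimated correlation for the other 3. GBP1, an interferon-induced GTPase, differed by 1.37 (SE 0.30), the chemokine genes CXCL10 by 1.83 and CCL2 by 1.55, and CD86, a costimulatory ligand on antigen-presenting cells, by 1.10. UBD, a ubiquitin-like modifier induced by cytokines (NCBI Gene ID 100294688), had the smallest p of the higher genes: 8.21 ± 0.24 in NEVKP and 6.85 ± 0.09 in No Storage (log2 value, SD, n = 3), a difference of 1.36 (SE 0.19, limma adjusted p = 0.299). ITGB3 (1.09), EVI2B (0.88), SPI1 (0.93), EVI2A (0.92), GPX8 (0.99), TMSB10 (0.71) and LGALS1 (0.97) followed on the higher side. ST3GAL1, a sialyltransferase (-1.39), PLA2G12B (-1.10), the nuclear receptor gene NR1I3 (-0.90) and CASQ2 (-0.78) had the smallest p on the lower side, all with a limma adjusted p of 0.299. UMOD differed by 0.19, SLC34A1 by 0.29, LCN2 by 0.24 and HAVCR1, again dim, by -0.05, with limma adjusted p from 0.85 to 0.951.

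In limma, 0 probe sets passed for NEVKP against No Storage, with 1735 at an unadjusted p under 0.05 and a smallest adjusted p of 0.299, and the count was 0 without any single array. Adjusted over the list alone, 17 of 27 interferon genes rose, including GBP1, IRF9 (0.87), PSMB9 (0.96) and LGALS9 (1.00), and 16 of 41 inflammatory genes, including CCL2, CCL4 (0.69), CSF1 (0.74) and CXCL10. Of 24 antigen processing genes, 12 rose and 1 fell adjusted over the list alone, led by the protease gene CTSS (0.73) and the class II genes SLA-DMB (0.64) and SLA-DMA (0.64) with the transporter gene TAP2 (0.90). Of 34 macrophage genes, 13 rose and 1 fell, led by SPI1, CD86, CTSS and TYROBP (0.76). The injury list had 11 of 34 members higher adjusted over the list alone (ITGB3 1.09, MYC 0.76, TIMP1 1.18, ANXA1 0.81), and the matrix list 4 of 36 (COL1A1 0.88, VCAN 1.24, COL1A2 0.62, TGFBI 0.98). The collecting duct list had 2 of 30 lower, the sodium channel genes SCNN1A (-0.55) and SCNN1G (-0.98), and the TCA list PC alone (-0.99). For all these members the count over all probe sets was 0 in limma. Of 33 fatty acid oxidation and 54 proximal tubule genes, 0 passed either way, with values of -0.63 for AGXT, -0.73 for PPARA, -0.80 for SLC37A4 and -0.73 for HNF4A.

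Camera with preset correlation placed 16 of 28 lists apart between NEVKP and No Storage, 11 higher and 5 lower. With an estimated correlation 0 passed, 6 lists having an unadjusted p under 0.05, and fry called 0. The interferon list had a median of 1.00 (camera adjusted p = 1.79e-16, and adjusted p = 0.248 with an estimated correlation). Its score per array, the mean over its genes relative to the No Storage mean, was 0.49, 0.55 and 1.86 in NEVKP replicates 1, 2 and 3, against -0.02, -0.38 and 0.40 in No Storage. Its median was 0.51 without NEVKP replicate 3. Medians were 0.69 for inflammation (adjusted p = 4.33e-14), 0.47 for injury (2.24e-11) and 0.45 for matrix (4.35e-14). They were 0.47 for antigen processing (4.09e-09), 0.43 for macrophages (9.77e-12) and -0.33 for collecting duct (2.00e-06). Each of these 6 lists had an adjusted p = 0.218 with an estimated correlation. For fatty acid oxidation (-0.37, adjusted p = 3.92e-09) it was an adjusted p = 0.248 with an estimated correlation, and for proximal tubule (-0.43, adjusted p = 2.28e-10) and smooth muscle (0.33, adjusted p = 0.000159) an adjusted p = 0.277 with an estimated correlation. For the TCA cycle (-0.18, adjusted p = 0.000159) it was an adjusted p = 0.266 with an estimated correlation, for apoptosis (0.19, adjusted p = 0.00161) an adjusted p = 0.236 with an estimated correlation, and for B and plasma cells (0.28, adjusted p = 0.00564) an adjusted p = 0.284 with an estimated correlation. Cell cycle genes (0.21, adjusted p = 9.6e-05) had an adjusted p = 0.529 with an estimated correlation, and NRF2 targets (-0.18, 0.0034) and T and NK cells (0.06, 0.023) an adjusted p = 0.359 with an estimated correlation. With centred arrays the T and NK cell median was 0.0020. In smooth muscle, CNN1 (0.88) rose and CASQ2 fell adjusted over the list alone, in the B cell list BANK1 (0.63) and CD40 (0.72) rose, and in the apoptosis list CASP1 (1.06) rose.

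Among the 12 lists that did not pass in NEVKP against No Storage were oxidative phosphorylation (median -0.02, camera adjusted p = 0.188), hypoxia (0.06, 0.487), complement (0.05, 0.122) and heat shock (0.08, 0.188). The others were endothelium (0.18, 0.0755), neutrophils (0.09, 0.687), red cells (-0.13, 0.287), fat and muscle (-0.09, 0.185) and 4 lists whose signs differed. The loop of Henle list had a median of 0.03, a mean of -0.10 and a downward test (camera adjusted p = 0.687). The podocyte list had -0.09, 0.05 and a downward test (0.862), the sterol list -0.0051, 0.0075 and a downward test (0.821), and the urothelium list -0.03, 0.01 and a downward test (0.821). Single arrays decided 4 list calls. These were NRF2 targets (-0.12 without No Storage replicate 2), T and NK cells (0.01 without No Storage replicate 2 and 0.10 without NEVKP replicate 1). They were also B and plasma cells (0.19 without No Storage replicate 2 and 0.22 without NEVKP replicate 3) and cell cycle (0.05 without No Storage replicate 3 and 0.11 without NEVKP replicate 1). The endothelium list passed without No Storage replicate 1 (0.21) or NEVKP replicate 3 (0.40). Oxidative phosphorylation passed without NEVKP replicate 2 (-0.07), and heat shock (0.15) and fat and muscle (-0.15) without NEVKP replicate 3. Calls kept with medians over 1.5 times smaller were inflammation (0.43), proximal tubule (-0.24) and smooth muscle (0.13) without NEVKP replicate 2. They were also interferon (0.51), NRF2 targets (-0.11) and TCA cycle (-0.12) without NEVKP replicate 3. In 6 further cases a median grew over 1.5 times.

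**Figure D2:**
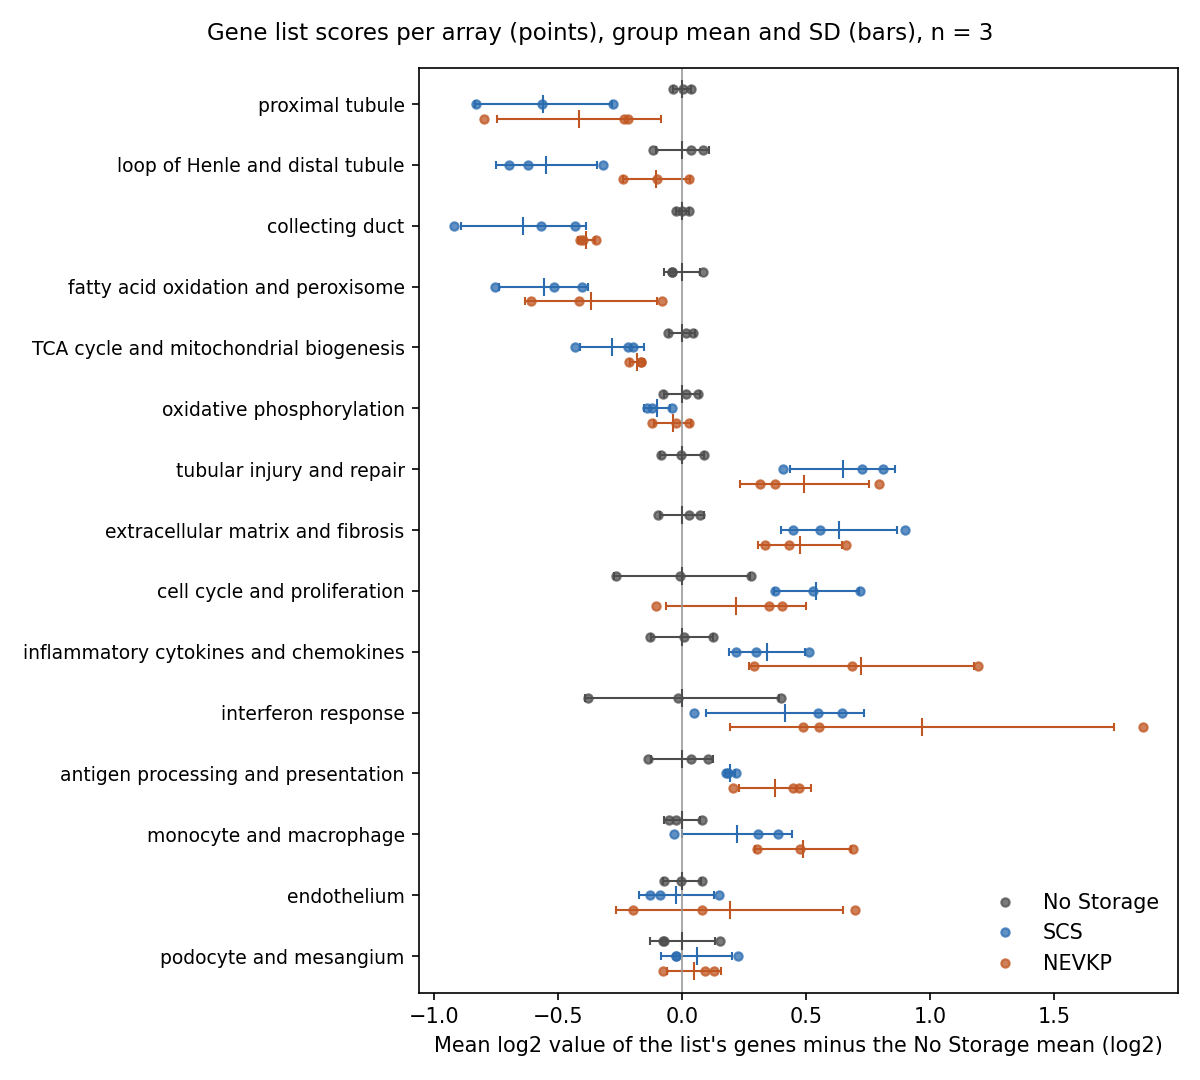
Scores of 15 gene lists (horizontal axis: mean log2 value of the list's genes minus the No Storage mean) in each array (points) of No Storage, SCS and NEVKP, with marks for the group mean and bars for the SD (n = 3). In SCS the tubule and fatty acid oxidation scores lie lowest and the injury and matrix scores highest, with the matrix mean at 0.63. The NEVKP interferon scores run from 0.49 to 1.86.

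The comparison of NEVKP with SCS asks how both ways of keeping a kidney for 8 h differ. In camera with preset correlation, the loop of Henle and interferon lists lay higher in NEVKP than in SCS and the cell cycle list lower. All had an adjusted p = 0.561 with an estimated correlation, and fry called 0 lists. Interferon scores per array were 0.64, 0.05 and 0.55 in SCS. NEVKP replicates 1 and 2, at 0.49 and 0.55, lay within that range. Cell cycle scores also overlapped, at 0.72, 0.37 and 0.53 in SCS and 0.40, 0.35 and -0.11 in NEVKP. Without NEVKP replicate 3 the interferon result ended (median 0.13) and the cell cycle median shrank to -0.18. UMOD was 12.38 ± 0.53 in NEVKP and 9.98 ± 1.10 in SCS (log2 value, SD, n = 3), a difference of 2.40 (SE 0.49, limma adjusted p = 0.439), and SLC12A1, the sodium-potassium-chloride cotransporter of the thick ascending limb, differed by 1.10. UBD differed by 1.49 (SE 0.19) and CDKL2 by 1.34 (SE 0.18), both with a limma adjusted p of 0.183, and the nucleoside transporter gene SLC28A2 by 1.10. RBP4 differed by -1.72 (SE 0.30, limma adjusted p = 0.314), the small heat shock protein gene HSPB8 by -1.07, the integrin gene ITGA3 by -1.25 and KRT18 by -0.89. The adrenergic receptor gene ADRA1B (0.81), RPS6KA6 (0.94), CASQ2 (0.88), LYRM7 (0.73), SLC38A11 (0.96), RYR2 (0.78) and SLC52A3 (0.91) were the others of smallest p on the higher side. LCN2 differed by -0.30, SLC34A1 by -0.73 and HAVCR1 by 0.01.

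In limma, 0 probe sets passed between NEVKP and SCS, with 1434 at an unadjusted p under 0.05 and a smallest adjusted p of 0.183. The count was 1 without SCS replicate 2, where UBD passed with 1.70 (adjusted p = 0.0389, range over its alternatives 0.0389 to 0.419). Adjusted over the list alone, and with 0 over all in limma, 3 of 24 loop of Henle genes rose (UMOD, KNG1 by 1.78, SLC12A1) and 4 of 33 complement genes rose (KNG1 and the macrophage-derived genes C1QB by 0.99, C1QC by 1.08 and C1QA by 1.03). The C1Q means in SCS, 8.84 (C1QB), 7.9 (C1QC) and 7.84 (C1QA), also lay below those in No Storage (9.47, 8.55 and 8.44). In 6 more lists 1 member each passed: KRT18 fell among injury genes, HSPB8 among heat shock genes and RBP4 among proximal tubule genes, while SLC25A4 (0.57), CASQ2 and BANK1 (0.65) rose in the TCA, smooth muscle and B cell lists. Of 27 interferon and 40 cell cycle genes, 0 passed, with values of 1.09 for GBP1, 0.98 for GBP2, -0.78 for AURKA and -0.65 for KIF2C.

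Camera with preset correlation placed 15 of 28 lists apart between NEVKP and SCS, 9 higher and 6 lower. With an estimated correlation 0 passed, 1 having an unadjusted p under 0.05, and fry called 0. Higher in NEVKP were the loop of Henle (median 0.38, camera adjusted p = 1.42e-05), interferon (0.53, 3.93e-07), macrophage (0.20, 0.000206), fatty acid oxidation (0.18, 0.00357), and antigen processing (0.27, 0.00465) lists. So were the inflammation (0.23, 0.00674), collecting duct (0.26, 0.0136), oxidative phosphorylation (0.08, 0.0316) and T and NK cell (0.10, 0.0361) lists. Lower were cell cycle (-0.32, 5.1e-09), matrix (-0.16, 0.00167), NRF2 targets (-0.26, 0.0021), injury (-0.17, 0.00357), neutrophils (-0.15, 0.0272) and heat shock (-0.08, 0.0367). Each of these 15 had an adjusted p = 0.561 with an estimated correlation, except heat shock with an adjusted p = 0.58 with an estimated correlation. The other lists had medians of 0.08 for the TCA cycle (camera adjusted p = 0.0836), 0.02 for hypoxia (0.844), 0.11 for complement (0.124), and -0.02 for apoptosis (0.585). They were -0.09 for sterol synthesis (0.401), 0.15 for proximal tubule (0.096), -0.08 for podocytes (0.163) and 0.19 for endothelium (0.096). They were 0.13 for smooth muscle (0.0902), 0.03 for B cells (0.161), 0.0015 for red cells (0.882), 0.02 for fat and muscle (0.669) and -0.08 for urothelium (0.295).

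Of the 15 lists that differed between NEVKP and SCS, only cell cycle, loop of Henle, NRF2 targets and macrophages passed without each single array, and the count of lists fell to 8 without NEVKP replicate 1. Without NEVKP replicate 3, the interferon list no longer passed (median 0.13), nor did antigen processing (0.18), oxidative phosphorylation (0.06), injury (-0.13) and heat shock (-0.02). Without NEVKP replicate 1, the lists of fatty acid oxidation (0.03), injury (-0.12), matrix (-0.11), heat shock (-0.05), collecting duct (0.09), neutrophils (-0.11) and T and NK cells (0.07) did not pass. Without NEVKP replicate 2, these were oxidative phosphorylation (0.04), inflammation (0.02) and T and NK cells (0.12). Without SCS replicate 1, they were oxidative phosphorylation (0.08), injury (-0.10), heat shock (0.01), collecting duct (0.11) and neutrophils (-0.01), the heat shock median changing sign. Without SCS replicate 2, they were oxidative phosphorylation (0.07), fatty acid oxidation (0.08), injury (-0.09) and matrix (-0.01). Without SCS replicate 3, they were inflammation (0.18), neutrophils (-0.23) and T and NK cells (0.08). The proximal tubule list passed without SCS replicate 3 (0.31) or NEVKP replicate 2 (0.35). Sterol synthesis passed without SCS replicate 2 (-0.30) or NEVKP replicate 2 (-0.17), and endothelium without SCS replicate 2 (0.25) or NEVKP replicate 3 (0.30). Smooth muscle passed without SCS replicate 2 (0.14) or NEVKP replicate 3 (0.26), B cells without SCS replicate 2 (0.15) and the TCA cycle without SCS replicate 3 (0.06). Calls kept with medians over 1.5 times smaller were cell cycle without NEVKP replicate 3 (-0.18), interferon without SCS replicate 2 (0.27) and antigen processing without SCS replicate 3 (0.13). In 16 further cases a median grew over 1.5 times. With array weights, oxidative phosphorylation (0.02) and inflammation (0.11) no longer passed, and without the dimmest probe sets oxidative phosphorylation (0.08), neutrophils (-0.19) and T and NK cells (0.11) did not. Array weights brought proximal tubule (0.16) and sterol synthesis (-0.20) past the threshold. Without both arrays of lowest weight, an alternative chosen after seeing the data, macrophages (0.07), oxidative phosphorylation (0.03) and inflammation (-0.088) no longer passed, and proximal tubule (0.17), sterol synthesis (-0.41) and B cells (0.18) did.

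Over all 3 groups, the F test of limma gave 1 probe set, CASQ2 (adjusted p = 0.0484), with 2442 at an unadjusted p under 0.05. CASQ2 had means of 8.44 in No Storage, 7.66 in NEVKP and 6.78 in SCS. The count was 0 without No Storage replicates 1, 2 or 3, SCS replicates 1 or 2, or NEVKP replicates 1 or 3, and was 9 without SCS replicate 3 and 2 without NEVKP replicate 2.

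The SCS and NEVKP differences from No Storage were compared across genes. All 31 probe sets called in SCS, led by CASQ2, SLC28A2 and TIMP1, had the same sign in NEVKP, with a median ratio of the NEVKP to the SCS difference of 0.385 (0.0693 to 0.885). They were chosen for their size in SCS and both differences use the same controls, so the ratio lies below 1 and the signs are shared in part by selection. At an unadjusted p under 0.05, 21 of the 31 differed between NEVKP and No Storage and 26 between NEVKP and SCS. Over all 19124 probe sets these counts were 1735 and 1434. The same selection can raise the 21 and the 26, so they add no test. The adjusted threshold in limma was passed by 0 in either comparison. Across 12355 genes, which are not independent replicates, the differences correlated at r = 0.665, against 0.4997 (0.464 to 0.534) for unchanged groups simulated against shared controls. The simulated genes were drawn independently, with the same spread in all groups. In the data genes can vary together and the groups differ in spread, so the simulated range does not show whether 0.665 exceeds chance. The sign was shared by 72.5% of genes, against 66.7% simulated. The covariance was 0.0636 against 0.0189 simulated, a difference of 0.0448. At an unadjusted p under 0.05, 305 genes were higher in both and 339 lower in both, against 49.7 and 53.3 for independent lists, and 3 had opposite directions. Independent lists leave out the shared controls, so this excess shows no shared effect by itself. The 3 No Storage arrays could not be divided into parts of at least 2, so part of the excess may come from the shared controls.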

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

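The tests of explanations for both patterns weighed here and their thresholds were chosen only after the result was seen, whereas the comparison with other splits of the arrays was planned. Of 296 items compared (28 lists and 268 named genes), 8 genes had every SCS array on one side of the No Storage mean and every NEVKP array on the other, and 0 lists did. None of the 8 passed in limma between NEVKP and SCS. Some named genes were chosen by small p in this same comparison, and no count by chance was computed. The 8 are therefore no test of opposite effects. The distance of single arrays from their group was described but not tested. Mean correlation with the own group was lowest for NEVKP replicate 2 (0.982) and SCS replicate 2 (0.983), the arrays of lowest weight.

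HSPB8, a small heat shock protein gene, was 0.50 above the No Storage mean in SCS and -0.58 from it in NEVKP, a NEVKP minus SCS difference of -1.07 (limma adjusted p = 0.314). REG3G, a secreted lectin gene (0.95 and -0.57, difference -1.52, limma adjusted p = 0.52), and SRXN1, an antioxidant gene (0.52 and -0.38, difference -0.91, limma adjusted p = 0.52), went the same way. CDKL2 (-1.12 and 0.22, difference 1.34, limma adjusted p = 0.183), ADRA1B (-0.41 and 0.39, difference 0.81, limma adjusted p = 0.243) and LYRM7 (-0.56 and 0.17, difference 0.73, limma adjusted p = 0.314) went the opposite way. So did PROM1 (-0.75 and 0.70, difference 1.45, limma adjusted p = 0.599) and NDUFB2, a respiratory chain gene (-0.27 and 0.04, difference 0.31, limma adjusted p = 0.648).

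Tubule lists lay lower and the matrix list higher in SCS than in No Storage. A lower share of tubule cells in the biopsy would raise all other compartments alike. The matrix score lay 0.61 higher relative to the mean of the podocyte and endothelium scores (pooled SD 0.0975, n = 3). The matrix rise belongs to the pattern itself, so only the podocyte and endothelium mean bears on this cause. That mean differed by 0.02 from No Storage (pooled SD 0.13, n = 3). A rise within this spread could be missed, and GATA3 counts in both the podocyte and the collecting duct list. The values thus argue only weakly against a lower tubule share as the whole cause. Other lists outside the tubule had scores of 0.13 (smooth muscle), 0.22 (macrophages) and 0.35 (neutrophils), and a change in the number of matrix-producing cells or an influx of leukocytes stays open. The neutrophil list also holds the injury marker LCN2. Macrophage genes went both ways, with means of 6.12 in No Storage and 7.15 in SCS for SPI1, and 8.44 and 7.84 for C1QA. Biopsies from another depth could move cortex and medulla in opposite ways. The collecting duct score (-0.64) was lower together with the proximal tubule score (-0.56). Both falls belong to the pattern itself, and the collecting duct list does not mark the medulla alone, so biopsy depth stays open. Without both arrays of lowest weight the proximal tubule median was -0.49, so these arrays did not carry it.

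The interferon list lay highest in NEVKP. Against SCS its median was 0.13 without NEVKP replicate 3 and no longer passed, so that result may rest on 1 animal. Against No Storage it was 0.51 without that array and still passed with preset correlation (camera adjusted p = 5.69e-09), but with all arrays it had an adjusted p = 0.248 with an estimated correlation. A larger share of immune cells in that biopsy was weighed with 4 immune cell lists. Their mean gap to the other NEVKP arrays was 0.0699 (SE 0.0582, n = 4 lists), against 1.34 for the interferon list. The SE covers lists within 1 array, not animals. Some list members, such as S100A9 and GZMK, were dim, so the test cannot decide the immune cell share. An infection or another event in this animal was not tested.

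Each comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05. The counts of splits as large include the real split. Fitted on the 6 arrays compared, SCS against No Storage gave 25 probe sets, with 1 as the highest of the other splits and 1 of 10 splits as large, and 17 lists, with 18 as the highest and 2 of 10 as large. NEVKP against No Storage gave 0 probe sets (highest other 3, 10 of 10 as large) and 16 lists (highest other 17, 3 of 10 as large). NEVKP against SCS gave 0 probe sets (highest other 3, 10 of 10 as large) and 14 lists (highest other 14, 2 of 10 as large). For the F test among groups, 14 of 100 splits, made up of the real one and drawn others, gave a count as large as the 1 found. The highest of the others was 5, so chance is not excluded.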

How the results depend on the processing

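Omission of both arrays of lowest weight was chosen only after the result was seen. The count of probe sets for SCS against No Storage, 31, was 83 with a trended and robust prior, 93 with array weights, 82 without the dimmest probe sets (fewer tested), 49 with centred arrays, 121 with the mean per gene and 0 (limma, 2814 unadjusted) without both arrays of lowest weight, and 0 to 158 without single arrays. The F test count, 1, was 5 with array weights, 4 with the mean per gene and 0 without both arrays of lowest weight (limma, 2253 unadjusted), and 0 to 9 without single arrays. NEVKP against SCS gave 1 with array weights and 0 to 1 without single arrays, and NEVKP against No Storage gave 0 throughout. List counts were 0, 0 and 0 with an estimated correlation and 4, 0 and 0 with fry for SCS against No Storage, NEVKP against No Storage and NEVKP against SCS. Without single arrays they were 14 to 17, 13 to 18 and 8 to 15, and the similarity was 0.600 to 0.701. The inflammation list between NEVKP and SCS reversed to a median of -0.088 without both arrays of lowest weight. The cause was not tested. The replicate block gave 27 probe sets for SCS against No Storage (17 shared) and 0 for the F test. Under it the neutrophil list lost its call for SCS against No Storage (0.22), while smooth muscle gained one there (0.32) and proximal tubule between NEVKP and SCS (0.15). Deviations of arrays with the same number correlated at -0.14 to 0.13, over 0.1 in 1 of 9 pairs, and 1 of 9 correlated best with its own number. These values show no pairing of the animals by number, but 9 pairs are too few to exclude it. Centred arrays brought smooth muscle (0.27) past the threshold in SCS against No Storage, and endothelium (0.13) and complement (median -0.0016 with an upward test) in NEVKP against No Storage. Calls kept with medians moved over 1.5 times were heat shock in SCS (0.07) and T and NK cells in NEVKP (0.0020) against No Storage with centred arrays, neutrophils in SCS against No Storage without the dimmest probe sets (0.40) and neutrophils between NEVKP and SCS with array weights (-0.23). Without both arrays of lowest weight they were TCA cycle (-0.11) and macrophages (0.39) in SCS, inflammation (0.43), proximal tubule (-0.24) and smooth muscle (0.13) in NEVKP against No Storage, and heat shock (-0.20) and neutrophils (-0.33) between NEVKP and SCS. The mean per gene ended the neutrophil call in SCS against No Storage (0.22). Without both arrays of lowest weight, sterol synthesis passed against No Storage in SCS (0.37) and NEVKP (-0.22), and oxidative phosphorylation in NEVKP (-0.065). For named genes, 3355 values kept their side of the threshold, 51 came past it and 41 fell short, and without single arrays 3305, 33 and 136. Most values that kept their side were never past the threshold. The 41 and the 136 all came from genes called in SCS against No Storage, most of whose calls were lost without single arrays. The lowest 25% of probe sets, under a log2 value of 3.92, limits what can be seen of dim genes such as HAVCR1.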

Other observations

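Gene families outside the fixed lists were defined by symbol and tested only after the result was seen, with 65 families of at least 15 genes per comparison. Ribosomal protein genes (RPL and RPS, 52 genes), which build the ribosome, lay higher in SCS than in No Storage, with a median log2 difference of 0.25 and 48 of 52 above 0 (camera adjusted p = 2.59e-09, and adjusted p = 0.55 with an estimated correlation). Between NEVKP and SCS their median was -0.15 with 47 of 52 below 0 (camera adjusted p = 3.34e-06, and adjusted p = 0.829 with an estimated correlation). Between NEVKP and No Storage it was 0.10 (camera adjusted p = 0.032, and adjusted p = 0.852 with an estimated correlation). With centred arrays the medians were 0.21, -0.16 and 0.05.

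Solute carrier genes outside the lists (202 genes) include SLC38A11, SLC28A2 and SLC52A3, which were already called in SCS, so the direction of the set in SCS is no independent test of lower transporter transcripts. Their median was -0.13 in SCS against No Storage with 131 of 202 below 0 (camera adjusted p = 0.00136, and adjusted p = 0.55 with an estimated correlation). The members of smallest p, named after their values were seen, were SLC38A11 (-1.60), SLC28A2 (-1.35), SLC52A3 (-1.26), SLC25A45 (-0.92), SLC16A4 (-1.82) and SLC15A2 (-1.41). Between NEVKP and SCS the median was 0.09 (camera adjusted p = 0.0968) and between NEVKP and No Storage -0.08 (camera adjusted p = 0.0868). With centred arrays the medians were -0.18 in SCS and -0.14 in NEVKP against No Storage and 0.09 between NEVKP and SCS. Tetraspanin genes (TSPAN, 15 genes) had medians of -0.20 in SCS against No Storage (camera adjusted p = 0.0341, and adjusted p = 0.55 with an estimated correlation) and 0.26 in NEVKP against SCS (0.0182, and adjusted p = 0.829 with an estimated correlation). With centred arrays the TSPAN medians were -0.25 and 0.25. Between NEVKP and No Storage, 2 more families passed with preset correlation: NUDT (15 genes, median -0.14, 13 below 0, camera adjusted p = 0.0301, and adjusted p = 0.626 with an estimated correlation) and CD (32 genes, median 0.10, 23 above 0, camera adjusted p = 0.032, and adjusted p = 0.852 with an estimated correlation). With centred arrays these medians were -0.20 and 0.05.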
